A study of Mus musculus with 12 samples.

How the data were processed

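RNA from laser-microdissected mouse epithelium was processed with a GeneChip WT Pico kit and carried a biotin label, per the labels' protocols, for 12 expression arrays. The deposited table held 1 column of log2 expression values per array. The submitters' processing notes named Partek and RMA, robust multi-array averaging, with no version. Any filter or further normalization by the authors is not given in the sources used here. The SD of the deposited values within an array ranged from 1.04 to 1.57, so the columns did not share one distribution. RMA normalizes probes before it summarizes them into probe sets, so this does not tell how RMA was applied.

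Probe sets were named from a table of the platform's annotation. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and were not named, and 12146 were unnamed here. Entrez identifiers of 21698 matched the reference table, and 0 symbols changed. Each gene took its probe set with the highest mean over the 12 arrays, which left 19938 genes, 999 of them with more than 1 probe set.

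Groups came from the labels. The genotype of 2 adjacent arrays was contradicted between title and source name on one side and description and genotype characteristic on the other, so those arrays entered no genotype comparison. Conflict array 1 is KO by title and floxed by characteristic, and conflict array 2 the reverse. The other 10 arrays were fitted together in 4 groups with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, two-sided, and Benjamini-Hochberg adjustment over the genes. A call is an adjusted p under 0.05. Tumor against adjacent over all arrays used 12 arrays and no covariate.

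Before the data were examined, 42 gene lists were written down, of pathways, epithelial cell types, other cell types and lengths of the intestine, with 1111 of their 1271 genes measured. Lists with at least 5 measured genes were tested, 40 in all, with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a comparison. Named genes followed a rule fixed at the same time: Ppard, S100a4, Ppara, Pparg and Apc, the 10 largest rises and falls among called genes with no overlap between arrays, the 5 smallest unadjusted p in each direction where fewer than 10 passed, and up to 4 members per described list. Predicted genes, microRNAs, snoRNAs and receptors of smell and the vomeronasal organ were counted but not named as the largest rises and falls. Folds of Ppara, Pparg and Apc in tumor epithelium were 0.09, 0.17 and −0.37, and none passed in any comparison with the settings given here. Among the alternatives, Pparg (−1.17) and Apc (−0.97) passed in tumor epithelium against the 1 floxed array left without weak-signal arrays, and Pparg (1.12) in adjacent epithelium with only the arrays compared.

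Same-numbered tumor arrays of the 2 genotypes deviated together, by title number, with correlations of 0.105 to 0.347 across genes in 3 pairs. By the rule set for such numbers, every pair above 0.1, they were treated as pairing the arrays, and the blocked count stands beside the result. The evidence was mixed, since 2 of the 3 pairs correlated best with their own number and floxed tumor array 2 did so with KO tumor array 1 (0.246 against 0.121). The 0.347 joined floxed tumor array 3 and KO tumor array 3, the arrays with the highest SD in their groups, 1.53 and 1.57. It therefore does not tell a shared source from a shared level of signal. Floxed tumor and adjacent arrays correlated at 0.177 to 0.601 by title number in 3 pairs that include a conflict array. The 0.601 came from floxed tumor array 3 and conflict array 2, the only arrays of their groups without weak signal, defined below. Floxed tumor array 1 correlated at 0.177 with its own number and with floxed adjacent array 2. These values therefore do not show that the numbers pair those arrays. No label states what a number shares.

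The lists were tested for both genotypes in tumor and in adjacent epithelium, for tumor against adjacent over all arrays and for the interaction, and, chosen after the data were seen, for tumor against adjacent within each genotype. Alternatives were other scaling of the arrays, a filter on dim genes, all probe sets, other variance options, array weights, other thresholds, only the arrays compared, each array left out, the replicate block, and both readings of the conflicting labels. Arrays of weak signal, defined by a median correlation with the others under 0.7, were left out in further fits chosen after the data were seen.

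The steps were tested on simulated data built from the gene means and the spread of each array, with 50 of 19938 genes changed at each of 4 sizes. For KO against floxed tumor, 24%, 78%, 86% and 96% of genes changed by 1, 2, 3 and 4 log2 units were recovered. These were 12, 39, 43 and 48 genes, and 20 unchanged genes were called beside them. False calls therefore made up a larger share of these calls than the threshold on adjusted p allows on average. In that comparison, calls on the real data may hold more false ones than the threshold implies. For tumor against adjacent in KO, 4%, 68%, 94% and 98% were recovered, with 0 unchanged genes called. A list shifted by −0.7 was called in both simulations, with 0 unshifted lists called for KO against floxed tumor and 1 for tumor against adjacent in KO. The simulated noise was independent between genes, so this cannot tell how often lists of correlated genes are called falsely.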

Results

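The series measured RNA in epithelium cut by laser microdissection from stained sections of intestinal tumors and of the epithelium beside them, in male mice on a C57BL6/J APCmin/+ background at 25 weeks. APCmin/+ mice carry an inactivated copy of Apc and form intestinal adenomas. The mice were either FSPCre-PPARB −/−, called KO here, in which Cre under the fibroblast-specific protein promoter removes Ppard, the nuclear receptor PPAR-beta/delta, or PPARB flox/flox littermates, called floxed here. Each sample was 1 array, and the labels did not tie arrays to animals, so arrays may share an animal, p-values over arrays may then be too small, and part of the spread between arrays may be technical. Nothing states that replicates came from separate animals. Tissue and genotype are named as the labels give them throughout.

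There were 12 arrays with 35556 probe sets each. The labels gave 3 floxed and 3 KO arrays of tumor epithelium, and 2 floxed and 2 KO arrays of adjacent epithelium. A further 2 adjacent arrays carried one genotype in the title and the other in the genotype characteristic, and entered only the comparison of tissues over all arrays. Tests ran on 19938 genes. The number of arrays limits the precision of every value.

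The arrays differed in signal, and this difference went with genotype. The 5 KO arrays correlated with each other at r = 0.947 to 0.973 over all probe sets. Floxed tumor arrays 1 and 2 and floxed adjacent arrays 1 and 2 correlated with all other arrays at 0.496 to 0.640, and are called weak-signal arrays here. Floxed tumor array 3 correlated with the KO arrays at 0.812 to 0.839. The SD of the log2 values within an array averaged 1.53 ± 0.03 (SD, n = 5) in KO and 1.16 ± 0.20 (SD, n = 5) in floxed arrays (exact permutation test, two-sided p = 0.0238, Benjamini-Hochberg p = 0.0238 over 3 measures).

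**Figure D1:**
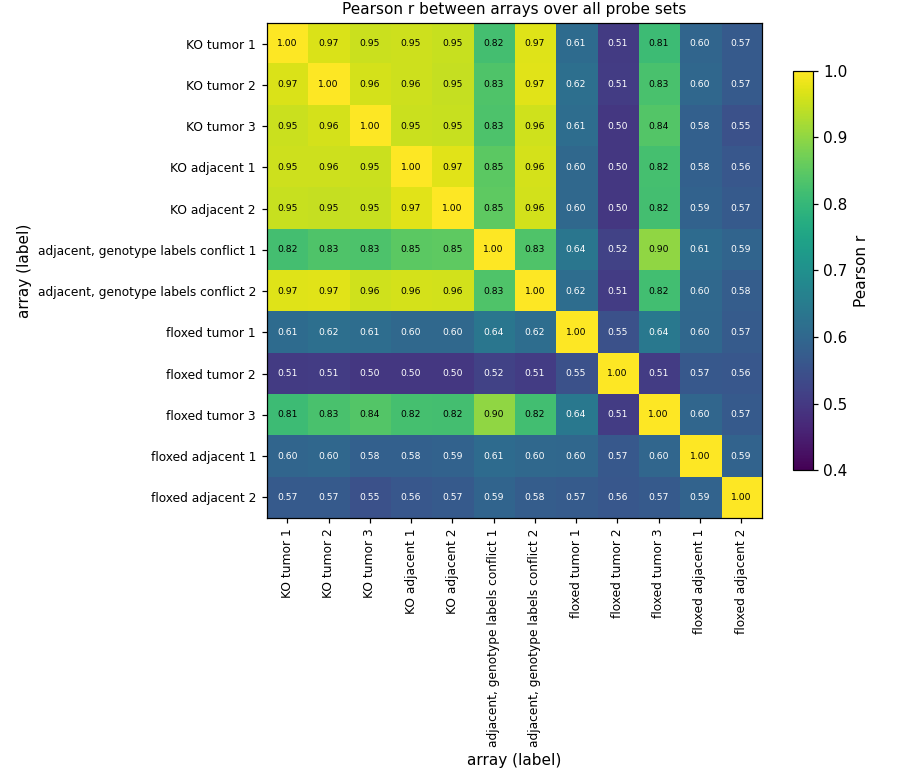
Pearson r between every pair of the 12 arrays over all probe sets, with arrays ordered by label on both axes and r in each cell. The KO arrays form a block at 0.947 or above, and the 4 weak-signal floxed arrays stay at or below 0.640 with every other array.

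Ppard, the floxed gene, was measured at 6.06, 6.07 and 6.50 (log2) in KO tumor arrays 1 to 3 and at 4.95, 4.48 and 5.79 in floxed tumor arrays 1 to 3. In adjacent epithelium it was 5.76 and 5.51 in the KO arrays and 5.09 and 4.61 in the floxed arrays. The arrays with conflicting labels held 5.76 and 6.13. KO minus floxed was 1.14 ± 0.33 (log2, SE, n = 3 and 3) in tumor epithelium with a limma adjusted p of 0.0991, and 0.78 ± 0.41 (SE, n = 2 and 2) in adjacent epithelium with an adjusted p of 0.230, so neither passed the test. In tumor epithelium it passed with the replicate number as a block (adjusted p = 0.0425), without floxed tumor array 3 (adjusted p = 0.0032), and with array weights (1.19, adjusted p = 0.0261), while the range of its adjusted p over all alternatives reached 0.307. The dissected tissue was epithelium and Cre acted in fibroblasts, and the position of the probes relative to the removed exons was not examined, so these values do not check the genotype labels. S100a4, the gene whose product is fibroblast-specific protein, differed by 0.90 ± 0.30 (SE) in tumor epithelium with an adjusted p of 0.125.

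The comparison the series title names set KO against floxed tumor epithelium. In KO tumor epithelium, Rpl5, a protein of the large ribosomal subunit, was higher by 4.35 ± 0.36 (log2, SE, n = 3 and 3; limma adjusted p = 0.00144). Cyp3a25, a cytochrome P450 of drug metabolism, was higher by 3.87 ± 0.48 (adjusted p = 0.00843), and Tns1, which links integrins to actin, by 3.86 ± 0.37 (adjusted p = 0.00229). The small noncoding RNAs Rny1 and Vaultrc5 rose by 3.86 and 3.77. Mcts1, a translation factor, fell by 2.31 ± 0.26 (adjusted p = 0.00648), and Defb38, a beta-defensin, fell by 2.26 ± 0.43 (adjusted p = 0.0462). In the KO tumor arrays Mcts1 lay at 2.79 to 3.22 and Defb38 at 2.07 to 2.29. The medians of unnamed probe sets there were 3.92 to 3.93, so the size of these falls is uncertain. For all genes named here floxed tumor arrays 1 and 2, of weak signal, made up most of the floxed group.

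In all, 215 genes passed, 136 higher and 79 lower in KO, and 782 with the replicate number as a block, 429 higher and 353 lower. Quantile normalizing the values again gave 13, 9 higher and 4 lower, 12 of them among the 215, and leaving out the dimmest 30% of genes left 98, 91 higher and 7 lower. With the conflicting labels read by title 0 genes passed (limma, 3813 at an unadjusted p under 0.05); no fold moved, as those arrays are labelled adjacent and altered only the shared spread. Usp17ld, Btnl5-ps, Taf1d, Acnat1 and Chd7 also belonged to the 10 largest rises that the naming rule allowed, between 3.02 and 3.45. Samt3, Dppa1, Dnajb7, Meioc, Klrc2, Prl2c5, Kcnt2 and Dthd1 completed the 10 largest falls, between −2.00 and −1.55. They lay at 1.94 to 3.19 in the KO tumor arrays, under the unnamed probe set medians of 3.92 to 3.93, so these folds are uncertain too. All 136 rises lay in genes above the median level of all genes in the KO arrays, against 2.53% of the falls. The KO arrays also set the direction of a call, so much of this split was fixed in advance. Olfactory and vomeronasal receptors made up 25 of the 79 falls, 31.6% against 6.06% of the genes tested, and microRNAs 9 of the falls and 8 of the rises, 11.4% and 5.88% against 1.51%. Small nucleolar RNAs made up 4 of the rises, 2.94% against 0.276% of the genes tested. The arrays of the 2 genotypes did not overlap in 5392 genes, 27.0% where chance gives 10% for 3 against 3.

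Of the 40 gene lists tested, 8 shifted in tumor epithelium (camera, adjusted p under 0.05). The detoxification and drug metabolism list rose by a median of 0.85 (log2, camera adjusted p = 1.2e-06), with 4 of its 41 measured genes past the test, among them Cyp3a11 at 2.93 and the carboxylesterase Ces2g at 1.78. Adjusted over the list alone, 12 passed. Absorptive enterocyte markers rose by a median of 0.86, with 1 of 37 past the test, the transcription factor Maf at 1.74. Lists of nuclear oxidative phosphorylation genes, ribosomal protein genes, fatty acid oxidation and cholesterol biosynthesis rose by medians of 0.72, 0.71, 0.58 and 0.45, with 1, 1, 0 and 0 members past the test in that direction. Eci2, an enzyme of fatty acid oxidation, was past the test the other way. Fibroblast and extracellular matrix markers rose by a median of 0.25, with Col3a1, a fibrillar collagen, at 1.21, and 5 of 37 past the test adjusted over the list alone. Neutrophil and mast cell markers fell by a median of 0.33, with S100a8, a granulocyte calcium-binding protein, at −1.39 past the test and 7 of 25 past it adjusted over the list alone. For each of these lists the adjusted p = 0.822 with an estimated correlation, so no call held. Without floxed tumor array 2, the enterocyte, oxidative phosphorylation, fatty acid oxidation and ribosomal calls were lost, with medians of 0.27, 0.35, 0.29 and 0.45.

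The PPAR target list had a median of 0.13 (camera adjusted p = 0.441), with 0 of 29 genes past the test. Acadm, which starts the oxidation of medium-chain fatty acids, differed by 1.51 with an adjusted p of 0.107.

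The 2 weak-signal floxed arrays weighed on these values. Without the weak-signal arrays, a setting chosen after the data were seen, KO tumor against floxed tumor array 3 gave 3866 genes, among them 211 of the 215, all 211 in the same direction, although that array had also helped to choose the 215. That fit held 1 floxed array, assumed to vary like the KO arrays, from which all its spread came. There the ribosomal protein, oxidative phosphorylation and enterocyte lists had medians of −0.60, −0.40 and −0.46, the opposite direction (camera adjusted p = 0.016, 0.0073 and 0.0903), and fibroblast and matrix markers one of 0.46 (camera adjusted p = 0.0029). With an estimated correlation each of these 4 had an adjusted p = 0.924. Neutrophil and mast cell markers had a median of 0.16 there (camera adjusted p = 0.828), and their scores were 4.43 and 4.35 in floxed tumor arrays 1 and 2 but 3.71 in array 3, within the 3.67 to 3.81 of KO tumor arrays. Exocrine pancreas and Brunner gland genes were 2.50 lower in KO than in that array. The detoxification and cholesterol biosynthesis calls were lost in that fit. Detoxification scores were 5.46, 6.06 and 6.06 in KO tumor arrays 1 to 3, against 5.47 in floxed tumor array 3. Cholesterol biosynthesis scores were 5.26, 5.20 and 5.53, against 5.25. With the replicate number as a block the count was 782, and it was 10 without KO tumor array 1 or 2, 14 without KO tumor array 3, 20 and 77 without floxed tumor arrays 1 and 2, and 5793 without floxed tumor array 3. Rpl5, Tns1 and Cyp3a25 were among the 10 without KO tumor array 1 and among the 10 without KO tumor array 2.

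In adjacent epithelium the same genotype comparison rested on 2 against 2 arrays, both floxed arrays of weak signal. Wfdc18, a whey acidic protein family member, was higher in KO by 5.08 ± 0.58 (log2, SE; limma adjusted p = 0.0046), Rpl5 by 5.07 ± 0.45 (adjusted p = 0.00156), and Agr2, a secretory-cell disulfide isomerase, by 4.31 ± 0.83 (adjusted p = 0.0242). Malat1 and Gas5, long noncoding RNAs, rose by 4.78 and 4.65, and Plac8 by 4.06. Zfp640, a zinc finger gene, fell by 4.43 ± 0.77 (adjusted p = 0.0193), and the interferon-inducible Ifi213 and the beta-defensin Defb1 fell by 3.22 and 2.75. In the KO adjacent arrays these falling genes lay at 1.32 to 2.54, under the median of unnamed probe sets there, 3.94. The size of their falls is therefore uncertain.

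There were 1209 genes past the test, 580 higher and 629 lower in KO. Quantile normalizing the values again gave 128, 84 higher and 44 lower, 127 of them among the 1209. Rpl37a, Rpph1, Vaultrc5 and Taf1d completed the 10 largest rises, from 4.16 to 5.06, and n-R5s136, Csmd3, Klk1b5, Wdr20rt, Srsy, Serpinb9d and Zfp600 the falls, from −4.12 to −2.46. Apart from n-R5s136, these falling genes lay at 1.77 to 3.65 in the KO adjacent arrays, under the unnamed probe set median of 3.94. Receptors of smell and the vomeronasal organ made up 203 of the falls, 32.3% against 6.06% of the genes tested. Small nucleolar RNAs made up 7 of the rises, 1.21% against 0.276%. Between the genotype comparisons of the tissues, 67 rises and 41 falls were shared, where independent lists would share 3.96 and 2.49. The comparisons came from 1 fit with a shared spread per gene, and both set KO arrays against weak-signal floxed arrays, so more sharing than that can arise without a genotype effect. Folds of the 2 comparisons correlated across genes at r = 0.725, and genes are not independent replicates.

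Of the lists, 18 rose in KO adjacent epithelium and none fell by camera at the preset correlation. With an estimated correlation 0 were called, and the smallest adjusted p was 0.136. Ribosomal protein genes rose by a median of 1.83, with 9 of 31 past the test and 19 past it adjusted over the list alone (adjusted p = 0.524 with an estimated correlation). Wnt/beta-catenin targets rose by a median of 0.70, with 6 of 34 past the test upward and 1 downward. The Wnt inhibitor Notum was higher by 2.12 and the cyclin Ccnd1 by 2.05. Intestinal stem cell markers rose by a median of 0.92, with 5 of 25 past the test, among them Gkn3 at 3.68 and Prom1 at 2.02 (adjusted p = 0.136 for both lists with an estimated correlation). Genes of fetal or regenerative epithelium rose by a median of 0.68, with 5 of 21 past the test, among them Clu at 2.96 and S100a6 at 2.67 (adjusted p = 0.136 with an estimated correlation). Adjusted over the list alone, 11 Wnt targets were higher and 1 lower, and 12 stem cell and 7 fetal or regenerative genes were higher. Calls fell to 10 without KO adjacent array 1, to 1 without array 2, to 427 and 215 without floxed adjacent arrays 1 and 2, to 1, Gkn3, with the conflicting labels read by title, and to 48 with them read by characteristic.

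Within the KO arrays, tissues could be compared between arrays of like signal, 3 labelled tumor and 2 labelled adjacent. Wfdc18 was lower in the arrays labelled tumor by 5.48 ± 0.53 (log2, SE; limma adjusted p = 0.0131), at 4.27 ± 0.24 (SD, n = 3) against 9.74 ± 0.19 (SD, n = 2). Gkn3, a gastrokine listed among stem cell markers, was lower by 4.06 ± 0.50 (adjusted p = 0.038), Clu, clusterin, a marker of regenerating epithelium, by 3.52 ± 0.45 (adjusted p = 0.0422), and Scd2, a fatty acid desaturase, by 2.63 ± 0.31 (adjusted p = 0.038). The arrays of the tissues did not overlap in 6393 genes, 32.1% where chance gives 20% for 3 against 2. Among genes higher in the arrays labelled tumor, the smallest unadjusted p belonged to Cyp3a11 at 3.65 ± 0.61, Cyp3a25 at 2.36, Cubn, a receptor of enterocytes, at 2.07, Slc5a11 at 1.38 and Entpd5 at 1.22, which did not pass here (adjusted p from 0.147 to 0.583).

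These 4 genes were all that passed when the spread was shared with the weak-signal floxed arrays. Fitted on the 5 KO arrays alone, the same comparison called 368 genes, 111 higher and 257 lower in the arrays labelled tumor, among them the 4. Cyp3a11, Cyp3a25, Cubn, Slc5a11 and Entpd5 passed as well in that fit (adjusted p = 0.0074, 0.0489, 0.047, 0.0277 and 0.0319). Of the 37 enterocyte markers 13 were higher and 0 lower there, and of the 34 Wnt targets 0 were higher and 11 lower. Notum and Nkd1, feedback inhibitors of Wnt signalling, were lower by −1.58 and −1.36 in that fit, Cd44 by −1.79 and Myc by −1.72. The sugar transporters Slc2a2 and Slc5a1 were higher by 2.09 and 2.36. These 6 were picked after their values were seen.

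Gene lists were tested in this contrast after the data were seen, and 24 shifted, 12 up and 12 down, 10 of them also with an estimated correlation. Wnt targets were lower in KO arrays labelled tumor by a median of 0.71, with 30 of 34 members below 0 and 10 past the test adjusted over the list alone (adjusted p = 0.00186 with an estimated correlation). Genes of fetal or regenerative epithelium were lower by 0.73, with Krt23 at −1.72 and S100a6 at −2.30 (adjusted p = 0.00186 with an estimated correlation), and stem cell markers by 0.34, with Prom1 at −1.39 (adjusted p = 0.0097 with an estimated correlation). MYC and ribosome biogenesis genes were lower by 0.50, cell cycle genes by 0.43 and DNA replication genes by 0.24, with 32 of 35, 35 of 36 and 39 of 44 members below 0 (adjusted p = 0.0097, 0.044 and 0.0103 with an estimated correlation). Fibrillarin, Fbl, was at −1.36 and the replicative helicase subunit Mcm7 at −0.78, neither past the test, while in the fit on the 5 KO arrays Fbl passed (adjusted p = 0.0293) and 6 of 35 MYC and ribosome biogenesis genes were lower. Krt23, S100a6 and Prom1 passed in that fit too.

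Absorptive enterocyte markers were higher in KO arrays labelled tumor by a median of 1.25, with 36 of 37 members above 0 (adjusted p = 0.0829 with an estimated correlation). Slc6a19 and Apoc3, a transporter of neutral amino acids and an apolipoprotein, were at 1.86 and 2.20, neither past the test. The detoxification list was higher by 0.82 with 40 of 41 members above 0 (adjusted p = 0.032 with an estimated correlation). Ribosomal protein genes were lower by 0.96 with 30 of 31 below 0 (adjusted p = 0.0709 with an estimated correlation). Each of the 4 single-gene calls was lost when any 1 of the 5 arrays was left out, while the Wnt median lay between −0.71 and −0.56 in those fits. None of the 5 arrays had weak signal. The conflict arrays, labelled adjacent, held Wfdc18 at 4.49 and 4.27, Scd2 at 3.48 and 4.40, Gkn3 at 8.87 and 4.34, and Clu at 8.81 and 7.46. With those arrays read by characteristic 0 genes passed (limma, 243 at an unadjusted p under 0.05) and the Wnt median was −0.44. Read by title, 3 genes passed, Gkn3, Clu and Krt23, named after their values were seen.

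**Figure D2:**
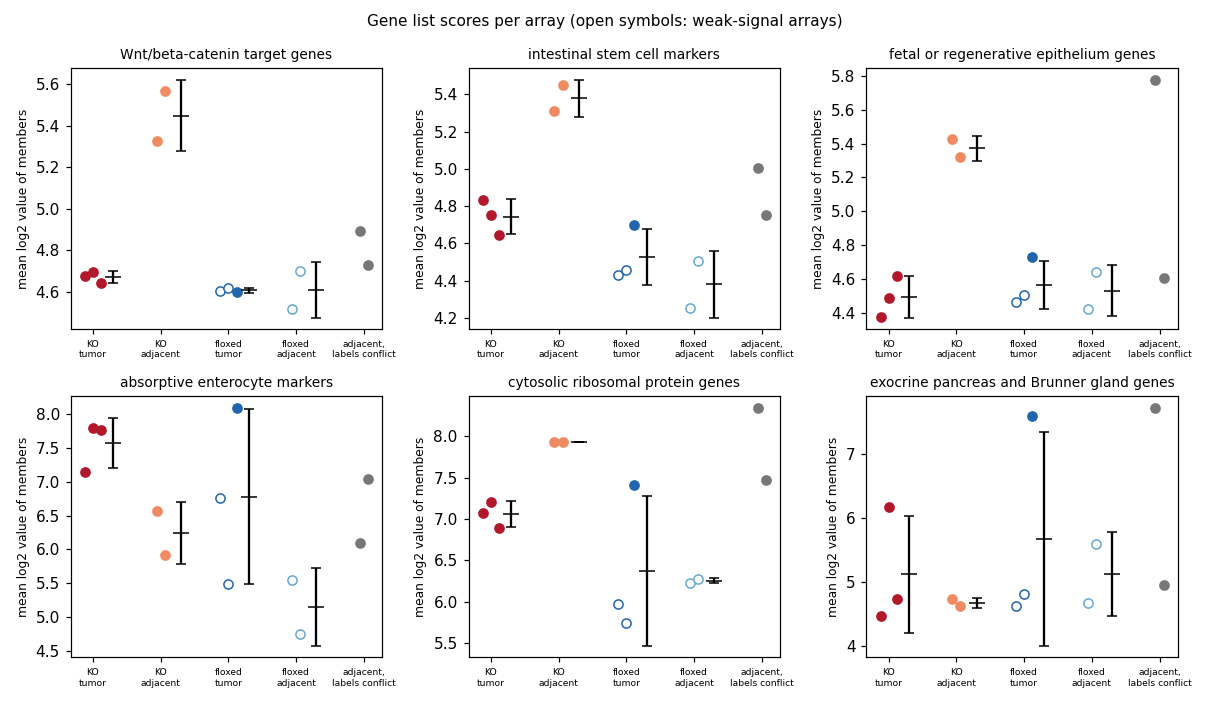
Mean log2 value of the measured members of 6 gene lists in each array, by group, with the group mean and SD beside the points of labelled groups. Open symbols are the 4 weak-signal arrays and grey symbols the 2 arrays with conflicting genotype labels. KO arrays labelled adjacent lie above KO arrays labelled tumor for Wnt, stem cell and fetal genes, and below them for enterocyte markers.

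Within the floxed arrays, 3 labelled tumor against 2 labelled adjacent, Snf8, a subunit of the ESCRT-II sorting complex, was higher in the arrays labelled tumor by 2.35 ± 0.26 (log2, SE; limma adjusted p = 0.0444), and it was the only gene past the test. Btf3, Rb1, Zcrb1 and Cdk9 had the next smallest unadjusted p among higher genes, between 1.45 and 2.31, and Xlr, Bloc1s5, Hoxc6, Chrna6 and Serpinb9d among lower ones, between −2.02 and −1.54, none past the test (adjusted p = 0.159). Enterocyte markers were higher by a median of 1.61, with 35 of 37 members above 0 (adjusted p = 0.769 with an estimated correlation), a list test chosen after the data were seen. Of the 5 arrays 4 had weak signal. The Snf8 call was lost without floxed tumor array 1 and without either floxed adjacent array. In that contrast 343 genes passed without floxed tumor array 2, and 8 without floxed tumor array 3. With the replicate number of the titles as a block 0 genes passed (limma, 2789 at an unadjusted p under 0.05).

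Over all 12 arrays, 6 labelled tumor against 6 labelled adjacent, no gene passed (limma, 0 genes, 513 at an unadjusted p under 0.05). The smallest unadjusted p among lower genes belonged to Slc44a2 at −0.90 ± 0.19 (log2, SE), Marcksl1 at −1.99, Qser1 at −0.89, Clu at −2.24 and Cd9 at −1.07. Among higher genes they were Sult2b1 at 0.83, Tmem161b at 0.69, Apoc3 at 1.67, Spink1 at 1.13 and H2-Bl at 1.22. Enterocyte markers were higher by a median of 1.25, with 36 of 37 members above 0 (camera adjusted p = 2.3e-29; adjusted p = 0.143 with an estimated correlation). Ribosomal protein genes were lower by 0.63, Wnt targets by 0.35 and fetal or regenerative genes by 0.41 (adjusted p = 0.243, 0.183 and 0.143 with an estimated correlation). PPAR targets were higher by a median of 0.36 with 27 of 29 members above 0 (adjusted p = 0.187 with an estimated correlation). The median of stem cell markers was −0.01 and their mean −0.24. Adjusted over the list alone, 11 enterocyte markers passed, among them Apoc3 and the glucose transporter Slc5a1 at 1.90.

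In the 8 arrays left without the weak-signal arrays, chosen after the data were seen, 0 genes passed and the enterocyte and Wnt lists had medians of 1.29 and −0.42. With genotype by title as a covariate 0 genes passed there (limma, 1432 at an unadjusted p under 0.05), and by characteristic 3 did, Slc44a2 at −1.09, Clu at −2.82 and the cytochrome Cyp2c67 at 0.94.

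**Figure D3:**
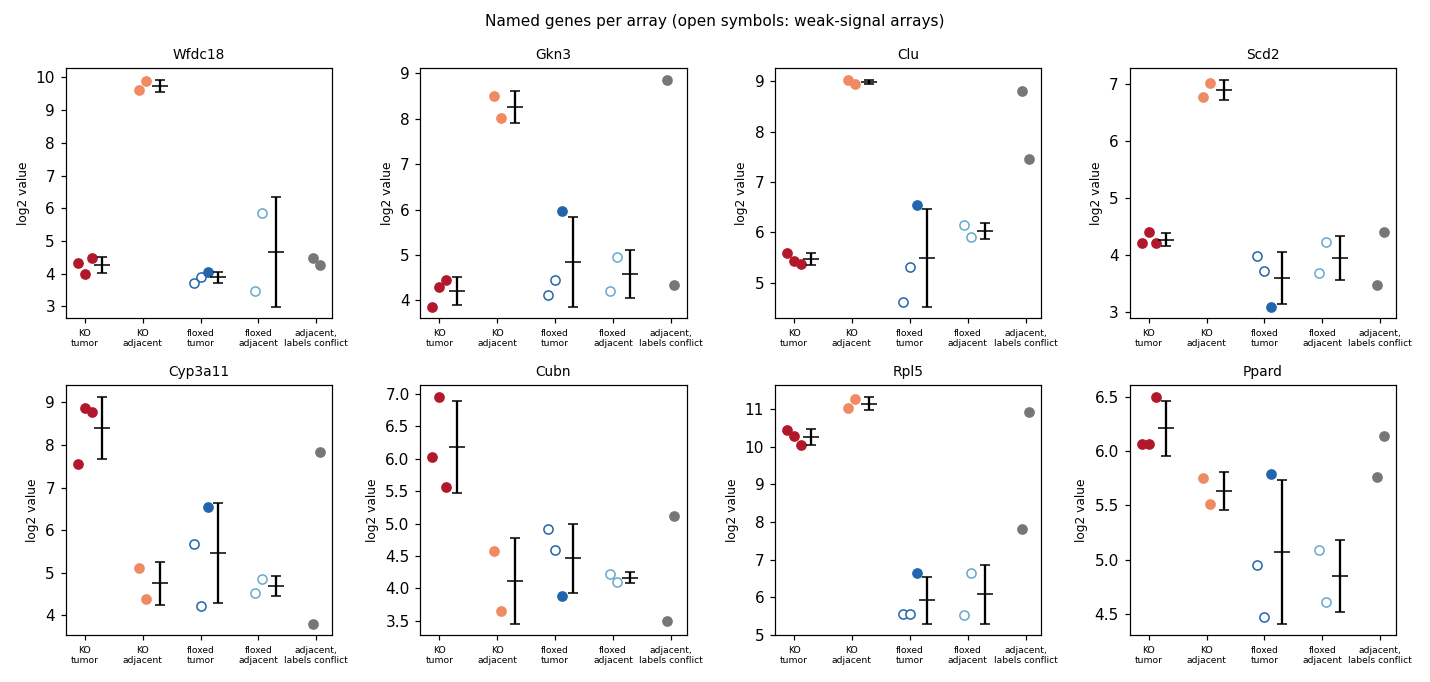
Log2 value of 8 named genes in each array, by group, with the group mean and SD beside the points of labelled groups, and open symbols for weak-signal arrays. Wfdc18, Gkn3, Clu and Scd2 are high in the 2 KO arrays labelled adjacent, and Rpl5 is higher in the KO arrays than in the floxed arrays.

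The last comparison asked whether the genotype difference depended on tissue. No gene passed (limma, 0 genes, 1281 at an unadjusted p under 0.05, smallest adjusted p 0.273). Ifitm2, an interferon-induced membrane protein, had the smallest p, with a genotype difference lower in tumor by 3.53 ± 0.47 (log2, SE). Wfdc18 at −4.70, Gkn3 at −4.32, Pglyrp1 at −2.63 and Snf8 at −2.23 followed, and Chrna6, Xlr, Trav7d-4, Bloc1s5 and Fbp1 led the other direction at 1.93 to 2.57. Of the lists 10 shifted, 9 of them lower, and 0 were called with an estimated correlation. Wnt targets had a median of −0.86 (camera adjusted p = 1.5e-07; adjusted p = 0.064 with an estimated correlation). Fetal or regenerative genes had −0.73 and ribosomal protein genes −1.04 (adjusted p = 0.0604 and 0.453 with an estimated correlation). All floxed arrays in this fit but floxed tumor array 3 had weak signal. Mean Wnt scores were 4.61 in floxed tumor and in floxed adjacent arrays, and 4.67 and 5.45 in KO tumor and KO adjacent arrays. The Wnt value thus mostly restates the difference between tissues within KO.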

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

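The tests of ribosomal genes, of exchanged tissue labels, of the title genotype and of signal measures in the conflicting arrays were chosen only after the results they bear on were seen, and so were the conditions on an interval and on the enterocyte list that decided the tests of crypt base and of intestinal lengths.

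Of 94 sets of 6 arrays of 1 tissue tested for a single array far from the rest, 5 held one, where chance gives about 4.7. Floxed tumor array 3 had an antimicrobial list score of 6.35 (mean log2 value of the list), against 5.29 in the next array labelled tumor. Floxed tumor array 1 had an enteroendocrine score of 4.32, below the next at 4.54. Conflict array 1 had an exocrine pancreas and Brunner gland score of 7.71, against 5.60 in the next array labelled adjacent, and a smooth muscle score of 5.03 against 4.60. Conflict array 2 had a B and plasma cell score of 5.33 against 4.53.

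The genotype difference itself differed between tissues for 10 lists by camera's test of the interaction. The medians, in log2, were −1.04 for ribosomal protein genes, −0.86 for Wnt targets, −0.73 for fetal or regenerative genes, −0.61 for stem cell markers and −0.60 for goblet cell markers. They were −0.44 for cell cycle genes, −0.48 for MYC and ribosome biogenesis genes, −0.42 for the unfolded protein response, −0.66 for antimicrobial genes and 0.17 for detoxification genes. None held with an estimated correlation, where the smallest adjusted p was 0.0604.

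The first pattern was the set of genes called between KO and floxed arrays labelled tumor, where the 10 splits of the 6 arrays are too few for a share under 0.05: the real split, the 1 that reached so many, called 215 and the highest of the others 0. The splits that parted all same-numbered pairs were only 4, and the highest of the others among them also called 0. Of 5793 genes called from floxed tumor arrays 1 and 2, 63.9% went the same way in floxed tumor array 3, 57.3% of those higher and 70.0% of those lower in KO. A share under 60% had been set beforehand for weak signal as the cause and one above 90% against it. Against floxed tumor array 3 alone 211 of the 215 were called again, but that array had helped to choose them, both sides used the same KO arrays and the share without any difference was not computed, so weak signal cannot be told apart from genotype. A difference in RNA composition could shift ribosomal protein genes, higher in both tissues (larger camera adjusted p 0.0113; adjusted p = 0.822 in tumor and 0.524 in adjacent with an estimated correlation) but at −0.60 against floxed tumor array 3 alone, and it follows the groups, so it and, untested, loss of Ppard in fibroblasts stay open.

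The second pattern was that Wnt and other tumor-associated genes were higher in KO arrays labelled adjacent than in KO arrays labelled tumor, though adenomas in these mice arise from loss of Apc. Exchanged tissue labels may account for it, since enterocyte markers were higher by a median of 1.25 in the arrays labelled tumor while Wnt targets were lower, but Wfdc18, 1 gene, lay at 9.61 and 9.88 in KO adjacent arrays and at most at 5.86 in any other array, whatever its label. Conflict array 1, labelled adjacent, also scored above floxed tumor array 3 for Wnt targets, at 4.89 against 4.60. For enterocyte markers it scored below that array, at 6.10 against 8.09, with 1 array on each side. Conflict array 2, also labelled adjacent, scored 4.73 for Wnt targets. KO arrays labelled tumor scored 4.64 to 4.69, and those labelled adjacent 5.33 and 5.57. Its enterocyte score was 7.04, against 7.14 to 7.79 and against 6.56 and 5.91. If that array is KO, as its characteristic says, it goes against the pattern and against a plain exchange of tissue labels. More crypt base in the adjacent dissections was to be excluded by a Paneth median at or above 0, and that median was 0.13. Resampling the 14 list members gave an interval of −0.91 to 0.44, which reaches the −0.3 that this explanation needs. That interval measures the spread between genes and not between arrays. In the fit on the 5 KO arrays alone, 3 Paneth markers were lower and 0 higher in the arrays labelled tumor. This explanation therefore stays open. Different lengths of the intestine were to be excluded by duodenum and ileum medians of the same sign, and the smaller was 0.38; that bound was ill chosen, because both lists hold villus genes and the enterocyte list itself moved by 1.25, so this also stays open. A lower Wnt output in KO tumors than beside them stays open and untested.

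The third pattern was the pair of adjacent arrays whose labels give both genotypes. Conflict array 1, KO by title, correlated at 0.900 with floxed tumor array 3 and at most at 0.852 with KO arrays, while conflict array 2, floxed by title, correlated at 0.956 or more with KO arrays. Among the rises named first for tumor epithelium, chosen without these arrays, Rpl5, Tns1 and Cyp3a25 were 7.82, 6.91 and 4.89 in conflict array 1. In conflict array 2 they were 10.9, 11.5 and 7.89. Floxed tumor arrays held at most 6.64, 8.11 and 5.41, and KO tumor arrays at least 10.05, 10.9 and 8.04. Rny1, at 7.57 in conflict array 1, lay nearer the KO tumor arrays. These genes were picked after their values were seen. The values may mean that the title genotype is the wrong one. The values argue against lower signal as the cause, since the SD of conflict array 1, 1.54, and its difference between named and unnamed probe sets, 0.570, lay within the KO ranges of 1.49 to 1.57 and 0.534 to 0.584, and its 95th percentile, 7.06, above the 6.78 to 7.02 of KO arrays, though its highest value, 13.4, lay under the 13.8 or more of KO arrays. A correlation above 0.5 between the differences of conflict array 1 and of floxed tumor array 3 from KO had been set beforehand against it and was met at 0.533, but that decides nothing, as it was 0.539 before expression level was corrected for, and both arrays held exocrine pancreas genes, so a shared tissue source or preparation stays open and untested.

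For all arrays labelled tumor against all labelled adjacent, 100 of 100 drawn splits called at least as many genes as the real split, which called 0 (limma, 513 at an unadjusted p under 0.05), and the highest of the others called 20. Any split reaches a count of 0, so this decides nothing.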

How the results depend on the processing

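Fits without the weak-signal arrays and the list tests within 1 genotype were chosen after the data were seen. The counts of genes called between genotypes moved with most settings. For KO against floxed tumor (215 genes), KO against floxed adjacent (1209), tumor against adjacent in floxed (1) and in KO (4), all probe sets gave 1366, 2948, 19 and 0 genes, array weights 2907, 4034, 0 and 1042, and only the arrays compared 8, 3435, 0 and 368. Quantile normalizing again gave 13, 128 and, in KO, 0, leaving out the dimmest 30% of genes 98 and 454, and an adjusted p under 0.10 gave 1181, 3346 and, in KO, 7. Trend and robust options gave 61 in tumor and 0 in floxed, and centred medians 0 in floxed and 2 in KO. Conflicting labels read by title gave 0, 1 and, in floxed, 0, and read by characteristic 132, 48, 0 and 0. Without 1 array the counts ranged from 10 to 5793, 1 to 427, 0 to 343 and 0 to 0. Where that left 1 array in a group, it was taken to vary like the other groups. Without weak-signal arrays KO against floxed tumor gave 3866. Over all 12 arrays the count of 0 became 127 with array weights and, without weak-signal arrays and with genotype by characteristic, 3 (by title 0), and it stayed 0 without each array in turn. The interaction count of 0 ranged from 0 to 1 without 1 array, with Glul past the test without floxed tumor array 1 and Wfdc18 without floxed adjacent array 2, both chosen after their values were seen. Of the 90 list calls, 10 held with an estimated correlation, all of them tumor against adjacent in KO. With fry 13 of the 90 held. Fry called 0 lists for KO against floxed tumor, 6 for KO against floxed adjacent, 5 for tumor against adjacent in KO and 2 for the interaction. The causes were not tested.

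Several folds changed sign. In KO against floxed tumor without weak-signal arrays, Pparg was −1.17 and Ppara −0.78, and medians were −0.46 for enterocyte, −0.40 for oxidative phosphorylation, −0.12 for fatty acid oxidation, −0.60 for ribosomal and 0.16 for neutrophil and mast cell lists. In that fit, with 1 floxed array, Pparg passed in the reversed direction (adjusted p = 0.027, where its alternatives ranged from there to 0.971), and so did the oxidative phosphorylation and ribosomal lists (camera adjusted p = 0.0073 and 0.016, adjusted p = 0.924 for both with an estimated correlation). Without 1 array Pparg ranged from −0.55 to 0.84 and Ppara from −0.19 to 0.52. In KO against floxed adjacent, Apc was 0.078 by title, and Pparg −0.045 and S100a4 0.047 by characteristic. Without 1 array Apc ranged from −0.49 to 0.00034 and S100a4 from −0.87 to 0.16. In tumor against adjacent over all arrays, Pparg was −0.0012 with array weights and −0.093 without weak-signal arrays, with or without genotype as a covariate. Without 1 array Ppard ranged from −0.0085 to 0.40, Apc from −0.0040 to 0.26 and Pparg from −0.19 to 0.50. Within floxed, Ppard was −0.21 by title and −0.081 by characteristic, Pparg −0.049 and Ppara 0.081 by characteristic, Ppara 0.032 with centred medians, and the goblet median −0.34 by characteristic. Without 1 array Ppard ranged from −0.14 to 0.52, Apc from −0.0013 to 0.54, Ppara from −0.46 to 0.25 and the oxidative phosphorylation median from 0.060 to 0.98. Within KO read by title, Apc was −0.069, Pparg −0.62, S100a4 0.11 and the NRF2 median 0.018. Without 1 array Apc ranged from −0.0038 to 0.29, Pparg from −0.15 to 0.26 and S100a4 from −0.24 to 0.097. For the interaction, Apc was 0.038 after quantile normalizing again and 0.038 by characteristic, where Pparg was 0.22, and without 1 array Apc ranged from −0.37 to 0.18.

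With the replicate block, counts were 782 in tumor, 2450 in adjacent and 0 in floxed, and 0 in KO by title or description numbers. In floxed, title numbers gave Ppard −0.14 and Apc −0.0013 in the block, and in KO Apc −0.0038 and Pparg −0.15. Same-numbered KO arrays of the tissues correlated from −0.081 to 0.080 by title and from −0.020 to 0.171 by description. The adjacent pairs across genotypes both gave 0.0099, fixed to be equal by the 2 arrays in each group. Such correlations over few arrays cannot tell whether a number stands for a shared source.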

Other observations

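The gene lists described here within KO arrays were tested after the data were seen. In KO arrays labelled tumor against KO arrays labelled adjacent, neutrophil and mast cell markers had a median of −0.14 and a mean of −0.38 (camera adjusted p = 5.7e-06; adjusted p = 0.185 with an estimated correlation), with 0 of 25 past the test over all genes and 4 adjusted over the list alone. Mcpt2 and Mcpt1, proteases of mucosal mast cells, were at −3.20 ± 0.44 (SE) and −2.97 ± 0.48, neither past the test (adjusted p = 0.0541 and 0.132). In the fit on the 5 KO arrays alone both passed (adjusted p = 1.6e-04 and 8.8e-04), with 5 of the 25 lower, and Mcpt2 also passed with trend and robust options (adjusted p = 0.0357). Antimicrobial and epithelial defence genes had a median of −0.35 (adjusted p = 0.044 with an estimated correlation), with Pla2g2a, a secreted phospholipase, at −3.64 and Lcn2, an iron-sequestering lipocalin, at −1.72, neither past the test (adjusted p = 0.0541 and 0.478). In the fit on the 5 KO arrays alone Pla2g2a passed (adjusted p = 0.0127), with 4 of the 26 lower. Interferon response genes had a median of 0.31 with 36 of 37 members above 0 (adjusted p = 0.310 with an estimated correlation).

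Genes of the exocrine pancreas, picked after their values were seen, were high in floxed tumor array 3 and conflict array 1. Sycn, a zymogen granule protein, was at 9.59 and 9.48 there, the chymotrypsinogen Ctrb1 at 9.29 and 8.90, and the carboxypeptidase Cpa1 at 9.11 and 8.86. KO tumor array 2 held Sycn at 7.41 and Ctrb1 at 7.91, and floxed adjacent array 2 held Sycn at 7.54. Conflict array 1 also had the highest Muc6 and Tff2, at 9.39 and 10.5. Conflict array 2 had the highest Cr2 and Cd22, genes of B cells, at 6.06 and 6.15.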
